A study of Mus musculus with 8 samples.

How the data were processed

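Region capture Hi-C was made from musculus by castaneus hybrid mouse cells with an Arima kit (3 ug of chromatin for ESC and iN), and enriched with Agilent SureSelect probes for mm10 chromosome 15, 71850001 to 73350000, per the labels. The series lists 8 samples. The 4 ESC and iN libraries (2 per cell type) and the B6xCAST cortex (2 replicates in 1 maternal and 1 paternal file) were used, in 10 deposited files; the CASTxB6 cortex was not analysed here. Per the submitters' processing notes, reads were aligned to mm10 with Bowtie2 and turned into contact lists with Juicer; versions, parameters and the allele caller are not given in these notes.

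The deposited files are contact lists with 1 line per read pair, split by allele by the authors, with no normalization. The other unit in the deposited files, besides positions in bp, is a mapping quality score for each end. The positions lay within the mm10 chromosome lengths in every file (0 ends beyond them). The strand columns hold only 0, so strand was not used. Genes were placed with the mm10 GENCODE annotation.

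Pairs with both ends in the captured region (1.5 Mb) were counted per allele in 75 bins of 20 kb, which make 2775 bin pairs. Same-bin pairs were left out. Between-bin pairs numbered 188228 to 254208 per library and allele in ESC and iN. Bin pairs with at least 20 pairs in every library, 2414 in all, were tested. For each library the value was log2 of first-allele over second-allele pairs, each plus 0.5, minus the log2 ratio of the library's between-bin totals. Contact frequency was log2 of the pairs of both alleles plus 0.5, scaled to the library's between-bin total (normalised pairs). Contacts of named features were counted between windows of 10 kb either side of the starts of 6 genes (15 pairs) and between 4 intervals divided at the starts of Kcnk9, Peg13 and Trappc9 (10 pairs, over 20 kb apart within an interval). At 56 bin borders, pairs joining 10 bins (200 kb) on each side were counted. Cortex values are single ratios with exact binomial 95% intervals (Clopper-Pearson) for counting error only.

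Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend), with 1 fit of the 4 libraries to cell type means and 2 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 over bin pairs, over the 25 feature pairs or over borders. Contrasts were ESC and iN against 0, and iN minus ESC. Counting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Where 1 replicate was left out, the lone library was assumed to vary like the other group.

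Genes and regions were named by a rule. It took every protein-coding gene with its start in the captured region, and Peg13, through contacts with Kcnk9, Peg13 and Trappc9; up to 5 bin pairs per contrast and direction with the smallest adjusted p, the libraries of the compared groups all having the sign of the contrast; and the highest and lowest border per cell type with the borders nearest the starts of Kcnk9, Peg13 and Trappc9. Groups, tests, this rule and the alternatives named next were fixed before the data were examined. Those alternatives were bins of 10 kb and 40 kb, at least 50 pairs or no filter, a pseudocount of 5, mapping quality of at least 30, identical positions counted once, centring on the median or per distance, iterative correction of bin coverage, an exact binomial test, limma with counting weights, a replicate block, windows of 5 kb and 20 kb, border windows of 5 and 20 bins, and leaving out each replicate. Chosen after seeing the data were subtracting misjoined pairs, leaving out the Trappc9 stretch without second-allele ends, centring contact frequency per distance (also without iN replicate 1), iterative correction before the border sums and in cortex, and the first 30% of cortex pairs in read order.

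Replicates were compared before testing. The chi-square per degree of freedom between replicates over bin pairs of both alleles was 1.08 for ESC and 15.8 for iN, and 270 of 351954 pairs over 20 kb apart in ESC replicate 1 had the same positions in replicate 2. Mate joining was checked by ordering pairs by their place on the sequencer and asking how often the first end of a pair lay within 5 kb of the partner end of the next pair, with the reverse order as control. Next pairs exceeded the control 2.89-fold and 3.24-fold in the affected G1 part and in G2 of iN replicate 1, 1.99-fold to 5.23-fold in cortex, and by 0.942-fold to 1.05-fold in the other parts. These values are for captured pairs on chromosome 15. Where misjoined pairs were subtracted, the share was set on pairs over 320 kb apart in iN replicate 1. Their frequency in its affected parts was made that of the unaffected G1 part. The share was 19.5% of G1 and 35.7% of G2. Far pairs were thus set alike in both alleles, and the tests took the share as known. On other chromosomes, 16 of 19 chromosomes tested in G1 and 18 of 18 in G2 of iN replicate 1, and 38 of 111 combinations of allele file and chromosome in the other ESC and iN libraries, had such misjoined ends, at up to 172-fold in G1 of ESC replicate 2. A segment of chromosome 6 was defined from 1 Mb windows with at least 200 ends and a G2 to G1 ratio under 0.25 in ESC, and enriched windows in cortex from a depth over 20-fold above ESC.

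The tests were tested on simulated data with the same depths (20 runs, 2775 bin pairs, 200 of them changed). The libraries of a cell type shared 1 simulated profile with a dispersion of 0.005. In these runs the difference between the iN replicates was therefore not simulated. For changes of 0.5 and of 1 in log2, the share called was 26.0% and 80.2% for ESC, 22.1% and 77.9% for iN, 8.08% and 44.1% for iN minus ESC, and 52.4% and 97.2% for contact frequency. False calls averaged 8.85, 3, 2.35 and 7.15 per run. With misjoined pairs simulated in iN replicate 1 and no true change, false calls averaged 0, 0.1 and 0.05 for the allelic tests and 0 for contact frequency. For borders (100 runs, 56 borders), differences of 0.2 were called in 30.2% with 0.16 false calls per run, and feature pairs gave 0.09. Each border was drawn independently, whereas real neighbouring borders share pairs, so these runs do not show the false calls for overlapping windows.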

Results

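The series asked how the 2 parental copies of the Peg13-Kcnk9 imprinted locus are folded and how that folding relates to imprinted Kcnk9 expression during neurogenesis. Chromatin contacts were measured by region capture Hi-C, in which ligated pairs of nearby DNA are enriched with probes, by the labels for mm10 chromosome 15, 71850001 to 73350000 (1.5 Mb). Mouse embryonic stem cells (ESC) and neurons induced from them and taken at day 6 (iN) gave 2 biological replicates each, and brain cortex of a B6xCAST cross gave 1 pair of files with 2 replicates pooled. In cortex 58.7% of autosomal ends also lay in 21 windows of 1 Mb outside chromosome 15, against 0.601% of those in ESC. The reciprocal CASTxB6 cortex was not analysed here. All cells carried a musculus and a castaneus genome, so pairs of read ends could be split by parental copy. The authors' files assign each pair as a whole.

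ESC replicates held 1703443 and 1556931 pairs for the first allele (named G1 in the deposited files) and 1585103 and 1450706 for the other (G2). iN replicates held 1701307 and 1750052 pairs of G1 and 1590726 and 1636345 of G2. Pairs with both ends in the captured region numbered 254918 to 289404 per allele in ESC, 306714 to 379701 in iN, and 558712 maternal and 406112 paternal in cortex. The share of pairs between chromosomes was 9.95% to 10.7% in ESC and 43.6% to 44.4% in iN. The labels do not state which parent G1 is. It was taken as maternal because pairs within the mitochondrial genome and within X were nearly all G1. In ESC replicate 1, pairs with both ends on X numbered 42564 for G1 and 189 for G2, and pairs within the mitochondrial genome numbered 48 and 0. For iN replicate 1 these counts were 19054 against 79 and 482 against 0. Single ends on X in its G2 file numbered 16375, so an end of a pair between chromosomes need not carry its file's allele. Below, log2 values are maternal over paternal pairs minus the library's own total ratio, so negative values mean more paternal contact. Mother and strain cannot be separated, since only 1 cross direction was analysed.

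Contacts of the paternal Peg13 with Kcnk9 exceeded those of the maternal copy in ESC and in iN. Peg13 (ENSMUSG00000106847.1, 72805600 to 72810324) is a noncoding RNA gene expressed from the paternal copy, lying inside an intron of Trappc9. Kcnk9 (ENSMUSG00000036760.7, 72501089 to 72546340) encodes a potassium leak channel expressed from the maternal copy in brain. Between windows of 10 kb either side of their start sites, paternal pairs were 2.60-fold more frequent in ESC, with log2 ratios of -1.45 and -1.31 (mean -1.38 ± 0.10 SD, n = 2, limma adjusted p = 1.04e-06). In iN they were 2.01-fold more frequent, with log2 ratios of -1.03 and -0.99 (mean -1.01 ± 0.03 SD, n = 2, limma adjusted p = 1.19e-04). The ratios rested on 99 maternal and 261 paternal pairs in ESC replicate 1, and on 129 and 240 in iN replicate 2.

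Trappc9 (ENSMUSG00000047921.16, 72589620 to 73061204), which encodes a subunit of a vesicle tethering complex, had the same paternal excess with Peg13 at its start site. The log2 ratios were -0.98 and -0.75 in ESC (1.82-fold paternal, limma adjusted p = 0.0304) and -0.50 and -0.97 in iN (1.67-fold, limma adjusted p = 0.0493). These calls were close to the threshold and ended when any of the 4 libraries was left out. The adjusted p was 0.643, 0.547, 0.0516 and 0.0582 for ESC, and 0.310, 0.319, 0.0744 and 0.187 for iN, without ESC replicates 1 and 2 and iN replicates 1 and 2. Peg13 contacts with Ago2, the slicing Argonaute gene (ENSMUSG00000036698.11), leaned the same way in 4 of 4 libraries without passing the test, with means of -0.70 in ESC (adjusted p = 0.212, limma) and -0.83 in iN (adjusted p = 0.0686, limma). Contacts of Peg13 with Chrac1 (ENSMUSG00000068391.8), a chromatin accessibility complex gene, averaged -0.68 and -0.46 (limma adjusted p = 0.254 and 0.437). Those with Col22a1 (ENSMUSG00000079022.10), a collagen gene, averaged -0.26 and -0.32 (limma adjusted p = 0.846 and 0.630). In iN replicate 2 alone these 3 contacts, with Ago2, Chrac1 and Col22a1, had -1.08, -0.56 and -0.47. With misjoined pairs subtracted, an alternative chosen after seeing the data, iN replicate 1 had 0.75, 0.11 and 0.98, and the iN means were -0.16, -0.23 and 0.26 (SE 0.48, 0.47 and 0.52, limma adjusted p of at least 0.758).

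No allelic difference was detected for the Kcnk9 start with the starts of Trappc9, Col22a1, Chrac1 or Ago2. Their means were -0.01, 0.39, -0.19 and -0.10 in ESC and 0.15, -0.17, 0.05 and 0.21 in iN (limma adjusted p of at least 0.630). Trappc9 with Col22a1, Chrac1 and Ago2 averaged 0.14, -0.30 and -0.13 in ESC and 0.01, -0.19 and 0.16 in iN (limma adjusted p of at least 0.22). The Peg13 window itself had slightly more paternal pairs with all partners together (log2 -0.24 and -0.23 in ESC, -0.22 and -0.31 in iN). Beyond that level its contact with Kcnk9 was still more paternal, by -1.21 and -1.07 in ESC and by -0.81 and -0.68 in iN.

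**Figure D1:**
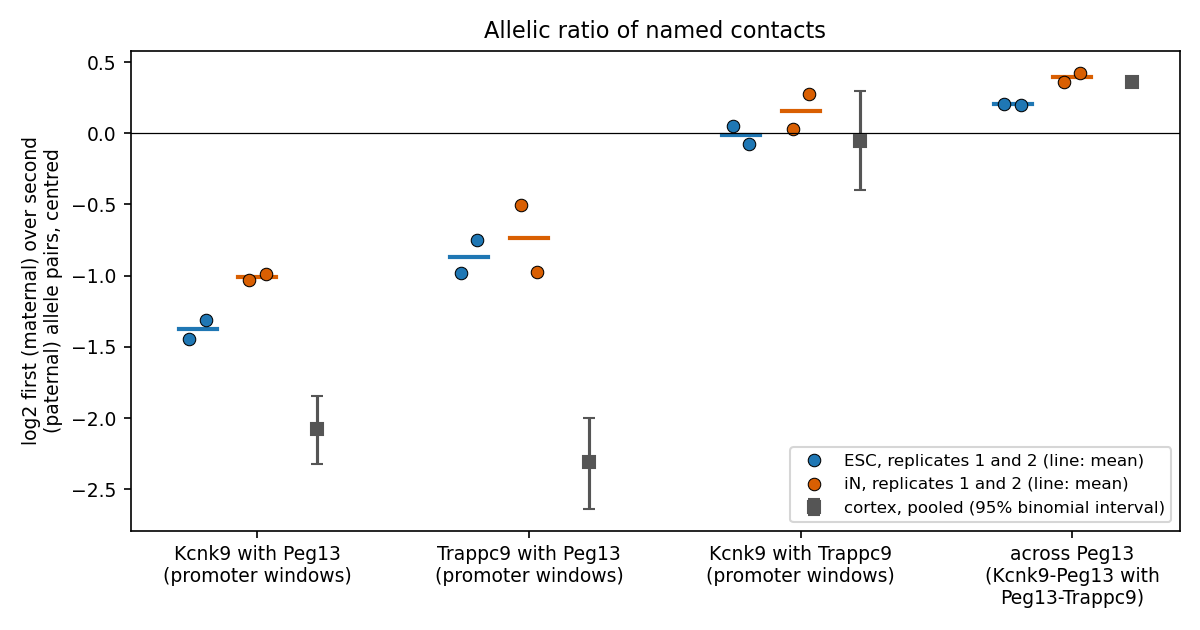
Log2 ratio of maternal (first allele) over paternal (second allele) pairs for the named contacts, per library, with cortex as 1 pooled value. Kcnk9 with Peg13 lies below 0 in every library, from -1.45 in ESC replicate 1 to -0.99 in iN replicate 2, and at -2.08 in cortex.

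The 2 intervals that flank Peg13 had more frequent contacts with each other on the maternal copy. The interval from Kcnk9 to Peg13 (264 kb) and the interval from Peg13 to the Trappc9 start (251 kb) touched each other 1.31-fold more often on the maternal copy in iN, with log2 ratios of 0.36 and 0.43 (limma adjusted p = 5.3e-04). In ESC the log2 ratios were 0.21 and 0.20 (1.15-fold, limma adjusted p = 0.126), which did not pass the test. The values of the other 3 interval pairs that span Peg13 depended in iN on iN replicate 1. With all libraries their means were -0.13 (captured start to Kcnk9 with Peg13 to Trappc9), -0.19 (Kcnk9 to Peg13 with the part beyond the Trappc9 start) and -0.12 (the 2 outer parts) in iN (limma adjusted p = 0.356, 0.160 and 0.437) and -0.08, 0.02 and 0.04 in ESC. Without iN replicate 1 they were -0.01, 0.002 and 0.15. With misjoined pairs subtracted they were -0.04, 0.23 and 0.29 (limma adjusted p = 0.224, 0.0191 and 2.17e-04), the last 0.24 above ESC (limma adjusted p = 0.0371). In the last 2, subtraction put iN replicate 1 at 0.46 and 0.42, above iN replicate 2 at 0.002 and 0.15. The tests took the subtracted share as known, so they decide nothing about these 2 contacts. Over all 908 bin pairs that span Peg13 the median was 0.03 in ESC and -0.04 in iN. The Peg13 to Trappc9 interval holds the Trappc9 stretch without second-allele ends, described below. Over the 817 spanning bin pairs that do not touch it the median was -0.01 in ESC and -0.07 in iN. The segment from the captured start to Kcnk9 touched the Kcnk9 to Peg13 interval less often on the maternal copy in iN (-0.32 and -0.15, mean -0.23, limma adjusted p = 0.0493), a call lost without either ESC replicate (limma adjusted p = 0.725 and 0.731) and a value of -0.15 without iN replicate 1. Of 25 contacts tested, 2 passed in ESC and 4 in iN, all named above. In ESC the number was 1 without either ESC replicate and 4 without either iN replicate, when the contact of the flanking intervals passed (limma adjusted p = 0.00487 and 0.00658). In iN it was 1 without either ESC replicate, 7 without iN replicate 1 and 12 without iN replicate 2; the call for the flanking intervals in iN was lost without either ESC replicate (limma adjusted p = 0.310 and 0.319).

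Over the whole captured region, 55 of 2414 tested pairs of 20 kb bins differed between the alleles in ESC, 36 with more maternal and 19 with more paternal contact (limma, 316 at an unadjusted p under 0.05). In iN 117 differed, 78 maternal and 39 paternal (401 unadjusted). Of these 117, 53 were called again in the same direction with iterative correction. With misjoined pairs subtracted, an alternative chosen after seeing the data, it was 79. Which direction had more calls depended on the settings. The maternal and paternal numbers were 27 and 27 with 10 kb bins, 21 and 21 with 40 kb bins and 8 and 11 with iterative correction in ESC, and 43 and 50 with 40 kb bins, 78 and 72 with counting weights and 175 and 185 with the exact binomial test in iN. The ESC count of 55 moved with each library, to 33 and 19 without ESC replicates 1 and 2, and to 101 and 108 without iN replicates 1 and 2. The bin that holds the Peg13 start (72810001 to 72830000), with 71 tested bin pairs, took part in 8 of the 19 paternal calls in ESC and 12 of the 39 in iN. Bin pairs on 1 side of it held 8 paternal calls in ESC and 18 in iN, and those that span it 3 and 9. Most of the Peg13 gene (72805600 to 72810324) lies in the bin before the start bin. Contacts of that bin with Kcnk9 count here among those on 1 side. In iN the Peg13 start bin also had 2 maternal calls. The bin at the Kcnk9 start met the Peg13 start bin with log2 ratios of -0.85 and -1.04 in ESC (adjusted p = 7.3e-06, limma), and the Kcnk9 gene body met it with -1.29 and -1.37 in iN (adjusted p = 4.64e-08, limma). In ESC the Kcnk9 body met it at a mean of -1.02, and 72550001 to 72570000, just beyond the Kcnk9 start, met it and the bin before it at means of -0.92 and -0.85. In iN the Kcnk9 body, the Kcnk9 start and 72070001 to 72090000 met the bin before the Peg13 start at means of -1.10, -0.85 and -1.21. Of the paternal calls, 14 were shared between ESC and iN.

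Maternal calls fell into 2 kinds. The strongest in both cell types, such as 72730001 to 72750000 with 72970001 to 72990000 in ESC (0.86 and 1.64), involved a 16 kb stretch of a Trappc9 intron (72964001 to 72980000) in which the second allele had almost no read ends, 7 against 3209 in ESC replicate 1. This stretch accounted for 30 of 36 maternal calls in ESC and 36 of 78 in iN, and for all 5 maternal bin pairs named in each cell type, whose means were 0.83 or more. Pairs joining its flanks were more frequent on the second allele, 283 against 120 in ESC replicate 1. All 24 maternal calls shared between ESC and iN touched it. Outside it, maternal calls numbered 6 in ESC and 42 in iN, and 39 of those 42 spanned Peg13. Among the paternal calls, a pair of neighbouring bins away from any gene start (72070001 to 72110000) had -1.11 and -1.21 in ESC (adjusted p = 1.39e-08, limma) and -0.77 and -0.92 in iN. These bins flank a 6 kb stretch with 0 to 2 ends on either allele in each library.

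With the intron stretch left out, an alternative chosen after seeing the data, there were 23 calls in ESC (4 maternal, 19 paternal), 20 of them among the 55 in the same direction, and 81 in iN (45 and 36), 77 of them among the 117.

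**Figure D2:**
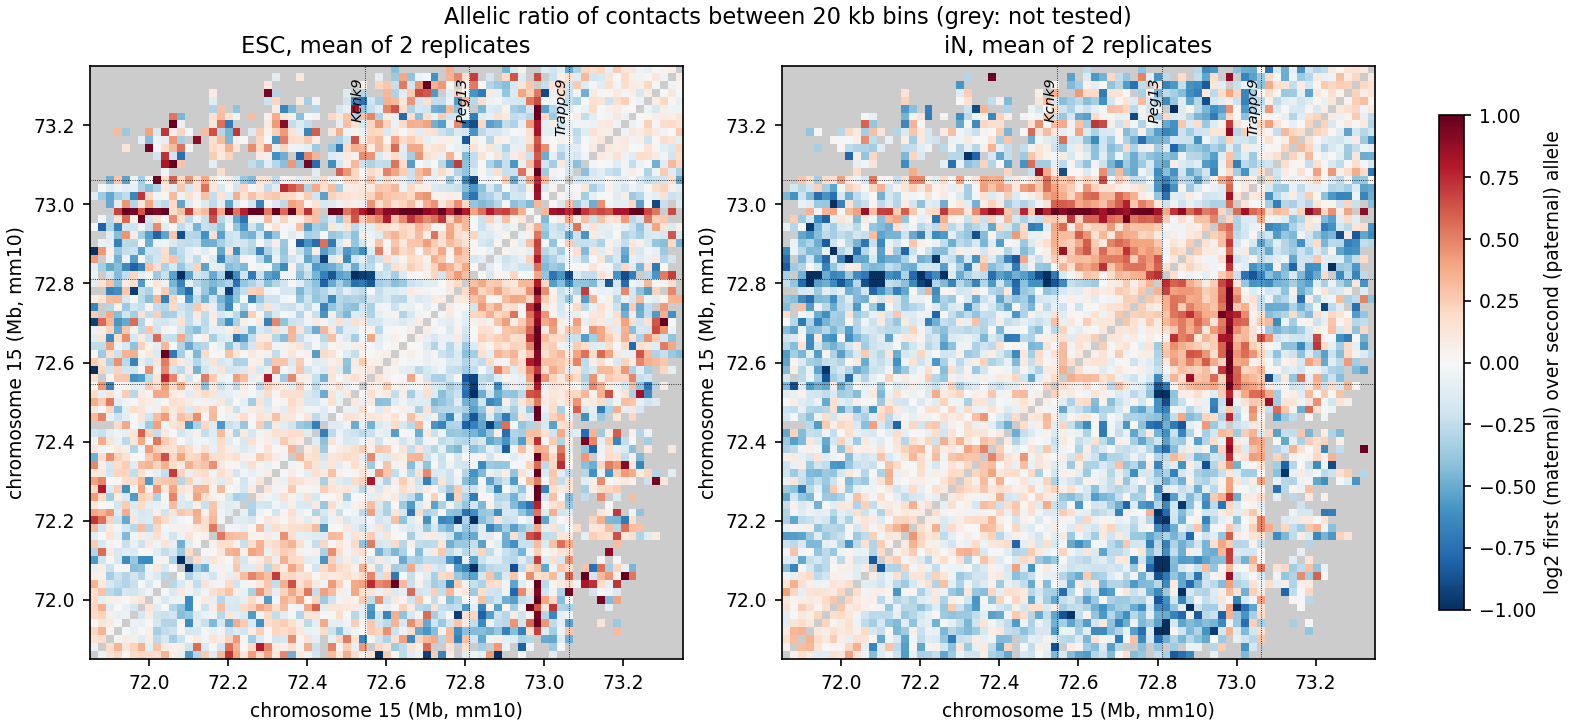
Log2 ratio of maternal over paternal pairs between 20 kb bins of chromosome 15 (both axes in Mb, mm10), mean of 2 replicates, for ESC and iN; grey bin pairs were not tested. A blue paternal stripe runs from Peg13 to and beyond Kcnk9, a red maternal block joins the intervals on both sides of Peg13 (mean 0.20 in ESC and 0.39 in iN), and the narrow red line inside Trappc9 is the Trappc9 stretch without second-allele ends.

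Where the alleles differed in contacts across a position was read from the pairs joining 200 kb on each side of 56 bin borders. The border nearest the Peg13 start, at 72810001, had the highest maternal excess in both cell types. It was 1.21-fold in ESC (log2 0.26 and 0.29, limma adjusted p = 0.00237) and 1.38-fold in iN (0.42 and 0.51, limma adjusted p = 1.29e-04). Borders with more maternal contact numbered 9 in ESC and 10 in iN, and those with more paternal contact 15 and 17. Centring on the median turned this balance round, to 14 and 17 maternal and 11 and 12 paternal. The lowest ESC border lay inside Trappc9 at 72650001 (-0.18 in both replicates, limma adjusted p = 0.0109), and the lowest in iN at 72090001 (-0.17 and -0.23, limma adjusted p = 1.29e-04). The latter lies in the nearly empty 6 kb stretch (72089001 to 72095000) named above. Its sum includes the bin pair around that stretch, with 452 maternal and 801 paternal pairs in iN replicate 2. How much that bin pair adds was not tested. Nearest the Kcnk9 start the ratio was -0.04 in ESC (limma adjusted p = 0.135) and -0.09 in iN (limma adjusted p = 0.00756), and nearest the Trappc9 start it was -0.05 (limma adjusted p = 0.372) and -0.15 (limma adjusted p = 0.00974). The Trappc9 call in iN ended without either ESC replicate and without iN replicate 1 (limma adjusted p = 0.0817, 0.0832 and 0.0602). The ESC total of 24 became 3 and 0 without ESC replicates 1 and 2 (limma; 9 and 6 at an unadjusted p under 0.05), where the Peg13 border had adjusted p = 0.288 and 0.314, and 36 without either iN replicate. The iN total of 27 became 49 without iN replicate 2.

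**Figure D3:**
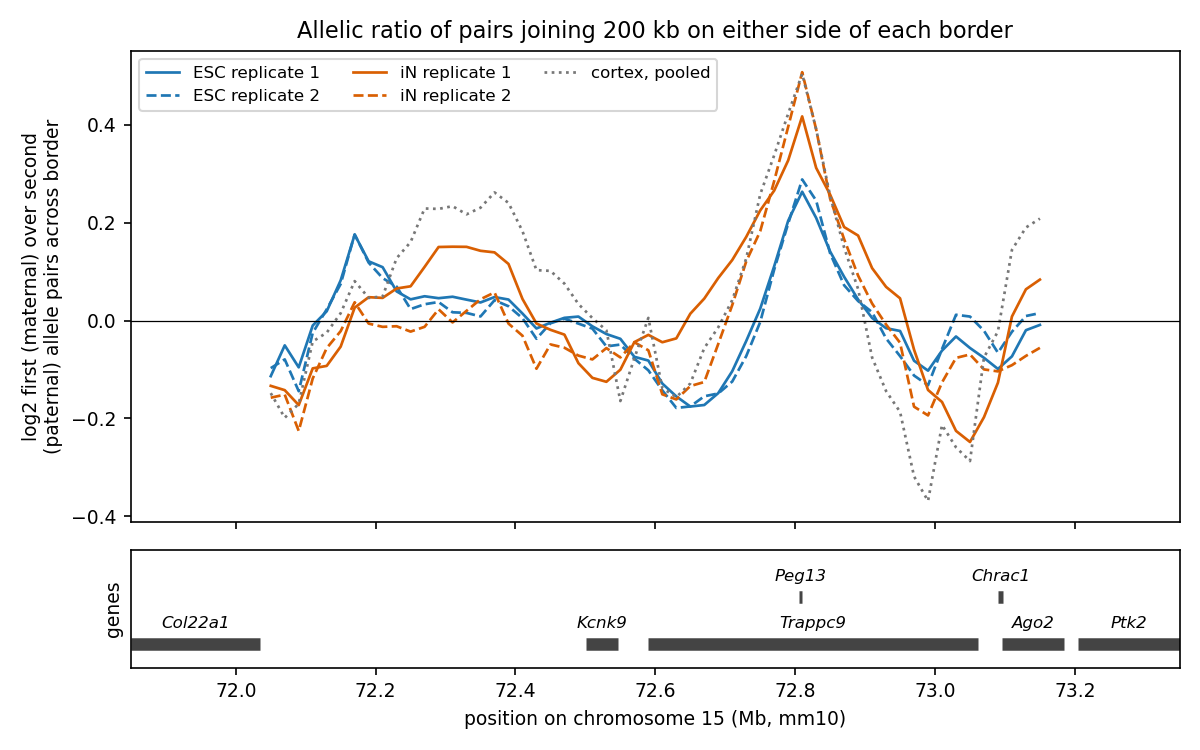
Log2 ratio of maternal over paternal pairs joining 200 kb on each side of each 20 kb bin border, along chromosome 15 (Mb, mm10), one line per library. All lines peak at the border nearest Peg13 (72810001), at 0.26 and 0.29 in ESC, 0.42 and 0.51 in iN and 0.50 in cortex.

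Whether the allelic structure changed on neuronal induction was tested as the iN minus ESC difference of the allelic ratios. At the Peg13 border the maternal excess rose by 0.19 from ESC to iN (limma adjusted p = 0.0480), with both iN replicates above both ESC replicates. The maternal over paternal ratio of contacts between the 2 flanking intervals rose by the same 0.19, which missed the threshold (limma adjusted p = 0.706). With misjoined pairs subtracted the rise was 0.26 (limma adjusted p = 2.62e-05), in a test that took the subtracted share as known. These contacts made up less of the pairs in iN on both copies. In ESC replicate 1 there were 21869 maternal and 18235 paternal ones beside 214618 and 206821 between-bin pairs. iN replicate 2 had 20974 and 14601 beside 254208 and 237835. The paternal excess of Kcnk9 with Peg13 did not detectably change (0.37 towards less paternal, limma adjusted p = 0.706). In all, 16 of 56 borders changed. Borders stand 20 kb apart and each sums 200 kb on either side, so neighbouring borders share pairs and are not separate observations. The 7 whose ratio moved towards maternal formed 1 run from 72690001 to the Peg13 border inside Trappc9. The 9 whose ratio moved towards paternal lay between 72070001 and 72190001, at 72490001 and 72510001 in the Kcnk9 body or next to it, and at 73010001 in Trappc9. With median centring 13 moved towards maternal and 4 towards paternal. With identical positions counted once 9 borders changed, and with windows of 5 and 20 bins it was 0 of 66 and 0 of 36 (limma, 1 and 2 unadjusted), with 0.25 and 0.11 at Peg13 (limma adjusted p = 0.894 and 0.397).

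Single bin pairs and named contacts gave 0 differences with limma, with 155 and 0 at an unadjusted p under 0.05. Simulated differences of 1 on the log2 scale were called in 44.1% of bin pairs at this design, and of 0.5 in 8.08%. The simulated iN replicates shared 1 profile, unlike the real ones, so these shares may be too high for these data. Without iN replicate 2, 45 bin pairs and 11 named contacts differed; without iN replicate 1 it was 0 bin pairs (150 unadjusted) and 1 named contact, that of the flanking intervals (0.22, limma adjusted p = 0.0149). The 16 borders became 0 without either ESC replicate (limma, 6 unadjusted in each case), where the Peg13 border kept its size (0.17 and 0.20) at adjusted p = 0.808 and 0.711, and 31 and 41 without iN replicates 1 and 2. Balancing the coverage of each bin in each allele, chosen after seeing the data, left 0 borders (limma, 13 unadjusted) and 0.13 at Peg13 (limma adjusted p = 0.161).

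Contacts of both alleles together also differed between ESC and iN in the limma test. The 2 iN libraries, however, differed more from each other (chi-square per degree of freedom 15.8) than from the ESC libraries (6.33 to 10.4). The share of pairs between chromosomes, given above, also differed between the cell types, so its effect cannot be told apart from theirs. Inside Ptk2, the focal adhesion kinase gene, 73210001 to 73230000 met 73330001 to 73350000 less often in iN, with log2 iN minus ESC of -1.17 (limma adjusted p = 4.62e-09) from 592 and 555 normalised pairs in ESC to 280 and 231 in iN. Contacts between the bodies of Ago2 and Ptk2 fell by 0.98 and by 0.93 in the named bin pairs, contacts of the Trappc9 body with the Ago2 start by 0.81 (limma adjusted p = 2.85e-06), and contacts of 72550001 to 72570000, next to the Kcnk9 start, with the Trappc9 body by 0.83 (limma adjusted p = 3.57e-06). Contacts that rose joined the 5' part of Trappc9 (73010001 to 73050000) to stretches 820 kb to 1100 kb away, by 0.88, 0.93, 0.82 and 0.82 in 4 of the 5 named bin pairs, which lay between 0.78 and 0.89 without iN replicate 1. The largest rise was with the Col22a1 body, from 172 and 140 normalised pairs in ESC to 588 and 249 in iN, and was 0.68 on the log2 scale without iN replicate 1.

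In total 121 of 2414 bin pairs changed, 14 up and 107 down (limma, 372 unadjusted). With contact frequency centred per distance, chosen after seeing the data, 20 changed (6 up, 14 down), and only 10 of the 121 were among them. Without iN replicate 1 all 5 rises and 5 falls named kept their direction. That fit takes its spread from the 2 ESC libraries alone, so its calls decide nothing about the named bin pairs. The distance profile of iN replicate 1 stood apart. In that library 30.9% and 31.7% of captured pairs were over 320 kb apart in the affected part of its G1 file and in its G2 file, against 14.7% in iN replicate 2 and 18.0% to 18.7% in ESC. The count depended on the libraries, at 0 and 7 without ESC replicates 1 and 2 (limma, 120 and 117 unadjusted), 835 without iN replicate 1 (165 up, 670 down) and 1195 without iN replicate 2 (706 up, 489 down). The direction by distance moved too. Bin pairs 660 kb or more apart had a median change of 0.49 with all libraries and 0.004 without iN replicate 1, and those 340 to 640 kb apart had -0.03 and -0.34, and those 20 to 100 kb apart had -0.13 (0 calls up, 28 down) and 0.03 (109 up, 62 down), while the fall at 120 to 320 kb stood at -0.25 and -0.33.

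**Figure D4:**
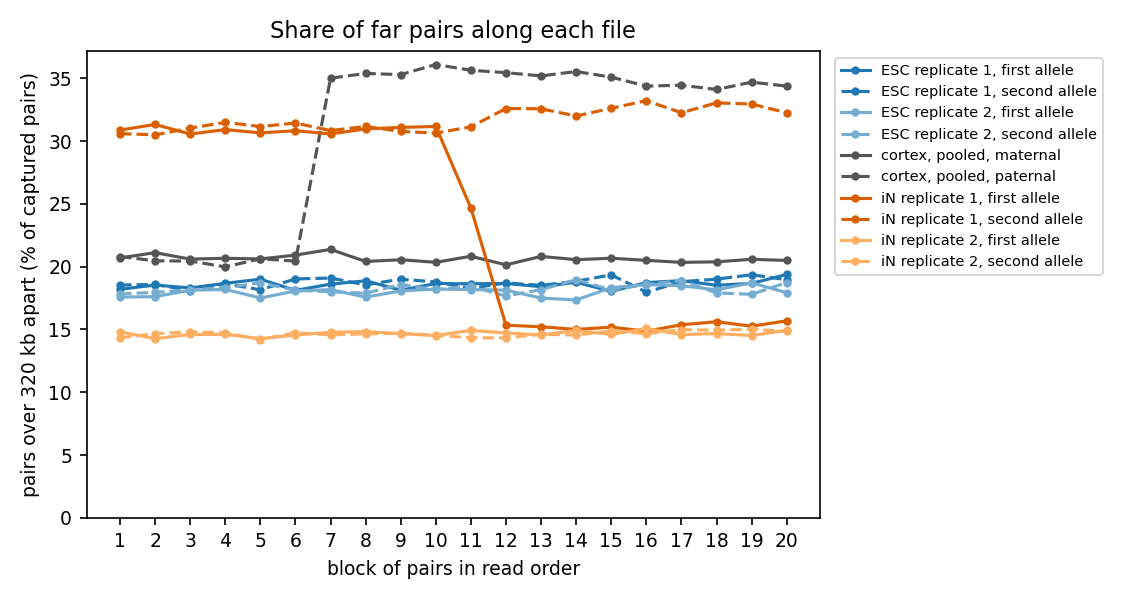
Percent of captured pairs over 320 kb apart in 20 blocks along the sequencer's read order (x axis), per library and allele. Each block holds an equal number of chromosome 15 pairs, but not of captured pairs. The first allele of iN replicate 1 drops from 30.9% to 15.3% after 57.0% of its captured pairs (in block 11). The paternal cortex file rises from 20.5% to 35.2% after 34.8% of its captured pairs (from block 7).

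In cortex, where the labels name the parents, contacts of Peg13 were paternal as well, and by larger ratios. Kcnk9 with Peg13 had 193 maternal and 665 paternal pairs, 4.22-fold more paternal (log2 -2.08, 95% exact binomial interval -2.32 to -1.85). For Trappc9 with Peg13 the ratio was 4.95-fold (-2.31, -2.64 to -2.00), for Peg13 with Chrac1 5.34-fold (-2.42, -2.89 to -1.99), for Peg13 with Ago2 3.53-fold (-1.82, -2.16 to -1.50) and for Col22a1 with Peg13 3.32-fold (-1.73, -2.15 to -1.33). Kcnk9 with Trappc9 was even (-0.05, -0.40 to 0.30), as was Kcnk9 with Ago2 (0.01, -0.34 to 0.38). Kcnk9 with Chrac1 was 1.99-fold more paternal (-0.99, -1.53 to -0.48) and Trappc9 with Ago2 more maternal (0.48, 0.38 to 0.58), but in the first 30% of pairs in read order, a part chosen after seeing the data, they had -0.31 (-1.30 to 0.70) and -0.14 (-0.32 to 0.04). Contacts between the 2 intervals flanking Peg13 were 1.29-fold more maternal (0.36, 0.34 to 0.39). The other 3 interval pairs that span Peg13 were more paternal, Kcnk9 to Peg13 with the part beyond the Trappc9 start 1.68-fold (-0.75, -0.78 to -0.71), the 2 outer parts 1.54-fold (-0.62, -0.65 to -0.59) and captured start to Kcnk9 with Peg13 to Trappc9 1.11-fold (-0.15, -0.17 to -0.13). In the first 30% of pairs the first of these was -0.21 (-0.29 to -0.13) and the other 2 reversed, to 0.16 (0.10 to 0.22) and 0.11 (0.07 to 0.16), while the flanking intervals had 0.31 (0.27 to 0.36). At the Peg13 border the ratio was 0.50 (0.47 to 0.54).

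The Peg13 window as a whole was also more paternal in cortex (-1.09 with all partners), and 4 kb at its start held 13304 paternal and 4440 maternal ends, a 4.12-fold larger share, a log2 ratio of -2.04 where ESC had -0.31 and -0.32 and iN -0.24 and -0.17. Beyond that window level, Kcnk9 with Peg13 stood at -0.99, within the range of the ESC and iN values, while Trappc9 with Peg13 at -1.22 (-0.75 to -0.28 in ESC and iN) and Chrac1 at -1.33 (-0.65 to -0.13) lay below theirs, and the difference between tissues was not tested. Of the 55 bin pairs called in ESC, 50 had the same direction in cortex (90.9%, exact 95% interval 80.0% to 97.0%), and of the 117 called in iN, 110 had it (94.0%, 88.1% to 97.6%), while 29.8% of all bin pairs were more maternal in cortex, and 51.9% in the first 30% of its pairs in read order, a part chosen after seeing the data, where 51 and 105 calls had the same direction. Of these calls, 30 of the 55 in ESC and 36 of the 117 in iN touched the Trappc9 stretch. The paternal cortex file lacks that stretch too (82 ends against 5083 maternal), so the agreement of those calls was fixed in advance. The maternal calls outside the Trappc9 stretch had the same direction in cortex in 3 of 6 for ESC and 37 of 42 for iN. Intervals of the contact ratios cover counting error only, since the 2 replicates were pooled. Those of the shares with the same direction treat called bin pairs as independent, which they are not. Both cortex files held ends joined to other pairs, the paternal file more so after a break in its read order.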

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

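Of the tests in this part, those of the distance profile and of the Trappc9 stretch at the Peg13 border, and that of misjoined ends for far pairs in iN replicate 1, were set before their results were seen, and the others were chosen only after the result was seen.

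The allelic contact ratio differed between iN and ESC at 16 of 56 borders by limma, and at the border nearest Peg13 the difference was 0.19 (limma adjusted p = 0.0480), which brought both to attention as differences between groups. Misjoined ends in iN replicate 1 are argued against as the cause, since the difference was 0.23 without that library, and so is the Trappc9 stretch without second-allele ends, with 0.19 when it was left out. A different distance profile would have lowered the difference within distance classes, where iN replicate 2 minus ESC averaged 0.23. Random ligation stays open, since its test, the lower iN replicate standing 0.13 above the higher ESC replicate, only restated the pattern, and so does allelic coverage of the bins, because balancing it took the difference from 0.19 (SE 0.06) to 0.13 (SE 0.04, limma adjusted p = 0.161), a smaller difference with both iN replicates (0.37 and 0.47) still above both ESC replicates (0.28 and 0.30), and the call also ended without either ESC replicate and with windows of 5 and 20 bins (0.25 and 0.11, limma adjusted p = 0.894 and 0.397), where 0 borders passed (1 and 2 unadjusted). A shift of the allelic ratio towards maternal across the Peg13 border with neuronal induction, the difference the design names, may therefore be held only as a hypothesis. The ratio does not tell more maternal contact from less paternal contact.

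In iN replicate 1, pairs over 320 kb apart made up 30.9% and 31.7% in G1 before a break in its read order and in G2, against 14.7% in iN replicate 2. A difference between the cultures as the only cause is argued against, because the share within the G1 file of 1 library fell by 15.7 percentage points at the break. The break was placed where this share changed most, so some fall there was fixed in advance. More random ligation is argued against as well, because pairs between chromosomes exceeded those of iN replicate 2 by at most 0.0151 percentage points. Ends joined to the partner of another read pair are the candidate cause that the tests left standing, since the pairs after the break differed from iN replicate 2 with a chi-square per degree of freedom of 1.69, against 8.48 for as many pairs before it and 1.13 between the ESC replicates at that number. A smaller difference between the cultures beside it stays open, since 1.69 lies above 1.13. At what step such joining would have arisen was not tested, and no biological explanation other than the culture was tested.

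Outside the captured region, a signal appeared on chromosome 6 from 44 to 95 Mb, where ESC replicate 1 had 1680 ends of the second allele and 47661 of the first and iN replicate 2 had 5351 and 34479, 0.0332 and 0.140 of the second-allele density of the rest of the chromosome; 51 of 2385 autosomal windows were this low, in 1 run. The end counts include pairs between chromosomes, whose ends need not carry their file's allele. Pairs within 1 Mb there numbered 12688 against 31 in ESC replicate 1 and 3227 against 8 in iN replicate 2, and cortex had 20535 maternal and 16049 paternal. Too few sequence variants are argued against, because the first allele kept 0.877 to 0.988 of the density of the rest of the chromosome and cortex held both alleles. Replacement by a duplicate of the first allele would have raised that density, which reached at most 0.988. Loss of the copy, for which 0.988 is what 1 remaining copy gives, may explain it as an untested property of the cell line; it is a hypothesis found and tested on the same data.

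In cortex, 21 windows of 1 Mb outside chromosome 15 had a depth over 20-fold above ESC, with 58.7% of autosomal cortex ends against 0.601% of those in ESC.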

How the results depend on the processing

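Subtraction of misjoined pairs, removal of the Trappc9 stretch, centring of contact frequency per distance, iterative correction of borders and cortex, and the first 30% of cortex pairs were chosen only after results were seen. Of the counts under an alternative, 102 stayed within 1.5-fold and 58 moved; of the named values, 153 kept direction and call, 43 lost the call, 7 gained it, 5 moved and 3 reversed. Except where stated, the cause was not tested.

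With 10 kb, 40 kb bins and median centring, allelic iN minus ESC gave 2, 2 and 2 bin pairs; contact frequency gave 187 with 10 kb and 59 with 40 kb bins. Iterative correction gave 19 bin pairs in ESC, 62 in iN and 0 borders for iN minus ESC (limma, 13 at an unadjusted p under 0.05). Exact binomial tests, which count only sampling error, gave 125 and 360 bin pairs and 14 and 14 named contacts in ESC and iN. Subtracting misjoined pairs gave 20 bin pairs in ESC, 393 for contact frequency, and 6, 9 and 2 named contacts in ESC, iN and their difference. Without the Trappc9 stretch, ESC had 23 bin pairs, since most of its calls touched it, and iN 2 named contacts. Centring contact frequency per distance gave 20, and 424 also without iN replicate 1. Named contacts in ESC were 1 with mapping quality 30 and 1 with median centring; in iN they were 2 with identical positions once, 2 with median centring and 2 with windows of 5 kb. Median centring left Kcnk9 with Peg13 at -1.31 in ESC and -0.87 in iN. Borders for iN minus ESC were 9 with identical positions once. With windows of 5 bins, borders were 1, 6 and 0 for ESC, iN and the difference, and with 20 bins 3 in ESC and 0 for the difference (limma, 1 and 2 unadjusted for the differences).

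Leaving out 1 library at a time gave ranges of 19 to 108 (bin pairs in ESC), 0 to 45 (iN minus ESC), 0 to 1195 (contact frequency), 1 to 4, 1 to 12 and 0 to 11 (named contacts in ESC, iN and difference), and 0 to 36, 19 to 49 and 0 to 41 (borders likewise). Trappc9 with Peg13, iN minus ESC, was 0.13 and reversed to -0.13 and -0.11 with windows of 5 kb and 20 kb and to -0.11 without iN replicate 1, 0.36 being the other end of that range; no form passed the test. Col22a1 with Peg13 in iN, outside these counts, reversed from -0.32 to 0.26 with misjoined pairs subtracted, as did 2 interval pairs spanning Peg13, from -0.19 to 0.23 and from -0.12 to 0.29. With the replicate block, allelic iN minus ESC gave 0 bin pairs (limma, 146 unadjusted) and contact frequency 137. Under it 6 bin pairs were called in ESC and 15 in iN, all among the 55 and 117, but as coded those tests were of the level in replicate 1 and not of the mean, with 1 residual degree of freedom. Correlations of the replicates' deviations were 0.0306 and 0.0688, and the labels share only a number between cell types.

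Kcnk9 with Peg13 kept its paternal excess and call in ESC (-1.67 to -0.86) and iN (-1.21 to -0.67) under all alternatives run. In cortex it was -2.36 with mapping quality 30 and -2.64 in the first 30% of pairs. Other cortex values reversed in that part, 2 interval pairs spanning Peg13 from -0.62 to 0.16 and from -0.15 to 0.11, and Trappc9 with Ago2 from 0.48 to -0.14. In simulations, changes of 0.5 in log2 were called in 26.0%, 22.1%, 8.08% and 52.4% of bin pairs for ESC, iN, their difference and contact frequency. Replicates shared 1 simulated profile, and depth and the number of replicates were not separated.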

Other observations

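Tests were not run for this part, and its regions were chosen only after their values were seen.

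Cortex reads were enriched at other imprinted regions beside Peg13 and Kcnk9. Of 17 imprinted gene clusters listed from general knowledge, that of Peg13 included, 7 others lay in windows with a depth over 20-fold above ESC. These were Peg10 and Mest on chromosome 6, Peg3, Snrpn, H19 with Igf2, and Kcnq1ot1 on chromosome 7, and Dlk1 with Meg3 on chromosome 12. At Dlk1 and Meg3, where the maternal copy expresses Meg3 and the paternal copy Dlk1, the window at 109 Mb had 665074 maternal and 561195 paternal ends (log2 0.25), beside 0.13 for all autosomes. At H19 and Igf2 the log2 ratio was 0.18, and at Kcnq1ot1 it was 0.14. The chromosome 7 windows at 59, 60, 61 and 62 Mb, which hold Ube3a, Snrpn, Ndn and Magel2, had more paternal ends, with log2 ratios of -0.11, -0.74, -0.86 and -0.78. Windows at 56, 57 and 58 Mb beside them had 0.21, 0.23 and 0.19, and the ESC ratios from 59 to 62 Mb were -0.05, 0.10, 0.05 and -0.01. Igf2r, Grb10, Gnas, Plagl1 and Nnat were among the clusters without such depth. These cortex values come from pooled replicates, and the ESC ratio of first over second allele is given for comparison without a test.

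Beside the Trappc9 stretch without second-allele ends, pairs joining its flanks favoured the second allele in all libraries, from 220 against 95 in iN replicate 1 to 424 against 136 in iN replicate 2, and 292 against 147 in cortex. The flanks of the empty 6 kb at 72089001 to 72095000 did so too, with 281 against 101 in ESC replicate 1 and 357 against 185 in cortex.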
